A study of Mus musculus with 2 samples.

How the data were processed

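Single-cell RNA sequencing libraries were made from bone marrow of Mettl1+/+ Mx1-Cre (WT) and Mettl1fl/fl Mx1-Cre (M1) mice with the 10x Genomics GEM-X 3' v4 chemistry, which counts the 3' ends of polyadenylated RNA and tags each molecule with a unique molecular identifier (UMI). Cells of 3 mice were pooled before each library, and no tag tells the mice apart. The source is labelled as mononuclear cells, but the preparation given is red cell lysis, which keeps granulocytes.

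The deposited values are counts, whole numbers of UMIs per gene and barcode, with no normalization. The file headers name Cell Ranger 9.0.1 and an integer matrix, and the submitters' processing notes name the genome build GRCm38. The annotation release is not given in the sources used here. Each barcode has at least 500 UMIs, so the files hold barcodes called as cells and not the full set of droplets. Whether some of these barcodes are empty droplets was not tested. Free RNA was read from cell types that should lack a gene. Of 32285 listed gene identifiers, 32158 were matched to GENCODE M21 for coordinates and lengths. There are 78 symbols used by more than 1 identifier, and these were kept apart by identifier.

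Barcodes with at least 500 UMIs, at least 250 genes and at most 10% mitochondrially encoded UMIs were kept. This removed 165 WT and 248 M1 barcodes for genes and 364 and 493 for mitochondrial share, some for both, and left 27637 and 28747. Doublets were called per library with scrublet as run by scanpy, at an expected rate of 0.4% per 1000 barcodes. It marked 1514 (5.48%) and 1743 (6.06%) barcodes, and these were removed. Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, chosen per library and combined, were scaled (limit 10), reduced to 30 principal components and joined with 15 neighbours. Both libraries were clustered together by the Leiden method at resolution 1, without batch integration, which gave 36 clusters.

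Each cluster was called by the class with the most fixed markers among its 10 leading genes by fold, ties going to the mean marker z-score. A name needed a mean z-score of at least 0.75 and at least 3 markers at 20 CPM or more and at least 2-fold above the other clusters; these thresholds were set after the data were seen. A cluster whose cells had a median UMI count under 1/3 of their library's and no marker among its leading genes would also have stayed unnamed. Cluster 31 failed these rules. Classes were led by Mecom, Meis1 and Hlf (HSC/progenitor-like), Elane, Prtn3 and Mpo (granulocyte-monocyte progenitor/promyelocyte-like), Ltf, Ngp, Camp and Fcnb (immature neutrophil-like), Retnlg, Mmp8, Stfa2l1 and Il1b (mature neutrophil-like, with 1 cluster led by the interferon-stimulated genes Rsad2 and Ifit3), Fn1, F13a1, Vcan and Ccr2 (monocyte-like), C1qa and Cd5l (macrophage-like), and Cd209a, Flt3 and Clec9a (conventional dendritic-like). Siglech and Cox6a2 led plasmacytoid dendritic-like, Prss34 and Mcpt8 basophil/mast cell-like, Vpreb1, Rag1 and Myl4 pro/pre-B-like, Cr2, Ighd and Ms4a1 immature/mature B-like, Jchain and Igha plasma cell-like, Themis and Cd8b1 T-like, Klre1 and Ncr1 NK/innate lymphoid-like, Hbb-bt and Hba-a1 erythroid-like, Pf4 and Ppbp megakaryocyte-like, and Fabp4 and Ldb2 stromal/endothelial-like cells. No cluster was eosinophil-like. These names rest on markers, not on a deposited annotation, so shares here may differ from any other naming of the same cells.

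With 1 library per genotype no test, p-value or standard error is given, and cells were not treated as replicates. Shares have exact binomial (Clopper-Pearson) intervals at 95%, UMI sums exact Poisson intervals, and M1/WT ratios exact conditional binomial intervals; all cover counting error only. Expression was compared in the 15 classes with at least 100 cells in each library, as UMI sums per library and class in CPM of the class. Genes with at least 50 UMIs over both libraries and a mean of at least 10 CPM counted as measured, and a count under 4 was set against a floor of 3 counts. The random lists behind each percentile numbered 10000, of the same size and matched in 20 expression bins. For the test of gene length they were matched in 6 bins of expression by 6 of length. A list needed 5 measured members. To compare shares of cells with a UMI, each cell was thinned to 3000 UMIs by drawing without replacement, and shallower cells were left out.

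The genes named were fixed by rule before the data were examined, as were the classes' markers, the gene lists and most of the other settings tried. Named were: Mettl1 and Wdr4; among genes measured in at least 6 classes with one sign in all of them, the 10 highest and 10 lowest medians; in each class, the 3 highest and 3 lowest ratios among genes with at least 200 UMIs whose interval excluded 1; and in each list, the 2 highest and 2 lowest members. Immunoglobulin and T cell receptor segments, mitochondrially encoded and ribosomal protein genes, Xist, Y-linked genes and unnamed gene models were left out of the parts on shared and class-wise genes. Genes for which 5 cells held over 50% of the UMIs of a class are named without values there, but such classes stay in medians over classes. Some list members taken by the rule, and 1 cluster marker, are not reported here, though they stay in the list medians and the naming of clusters. Hmga2 and Igf2bp3 fall outside the rule and were chosen after their values were seen.

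The 32 gene lists cover tRNA modification enzymes, aminoacyl-tRNA synthetases, ATF4 targets, p53 targets, interferon-stimulated genes, S phase, G2/M phase, ribosomal proteins, translation factors, ribosome biogenesis, mitochondrially encoded genes, oxidative phosphorylation, glycolysis, the unfolded protein response, NF-kB, immediate-early genes, apoptosis, histones, primary and specific granules, late neutrophil maturation, MHC class I and II, the pre-B receptor, stem cell genes, erythroid genes, monocyte/macrophage genes, cholesterol synthesis, the proteasome, mitochondrial ribosomal proteins, chromosomal neighbours of Mettl1 and free RNA markers. Some lists share genes: 3 of the 15 MHC class I genes are also in another list, and 4 of the 12 specific granule genes.

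The calculation was checked on counts simulated by independent Poisson draws from the immature neutrophil-like and HSC/progenitor-like sums. The draws held no spread between cells or mice and no free RNA, and the lists were random genes. Coverage near 95% was thus built in. The check does not show how intervals or percentiles behave on real counts or on lists of genes that vary together. Intervals covered the true ratio for 95.4% and 95.8% of unchanged genes. Of genes set 1.5-fold apart, 100% and 94.0% had an interval that excluded 1. Of 100 unchanged lists, 98 and 96 lay inside the central range of random lists, and of 100 lists of 20 genes raised 1.2-fold, all lay above it in both classes.

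Alternatives tried were no cell filter, a stricter one (1000 UMIs, 500 genes, 5% mitochondrial), doublets kept, resolutions of 0.5 and 2, a per-cell marker score, each library clustered alone, shares among cells outside the neutrophil classes, scaling without the 20 most abundant genes and without ribosomal, mitochondrial, haemoglobin and immunoglobulin genes, trimmed-mean (TMM) factors (30% of log ratios and 5% of levels trimmed), low genes kept (10 UMIs, no CPM minimum) and means of per-cell CPM. Alternatives chosen after seeing the data were counts of HSC/progenitor-like cells without clusters (with thinning to 5000 UMIs, without it, and with WT marker UMIs lowered at random to the M1/WT ratio of the class), list medians without the macrophage-, megakaryocyte- and T-like classes, the erythroid-like class without its low-UMI cluster, and clustering without the 973 genes that differed between the libraries within a class, which left 91.0% of cells in the same class. Python 3.11.15 was used with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.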

Results

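Bone marrow of 2 mouse genotypes was profiled by droplet-based single-cell RNA sequencing, to ask how Mettl1 shapes the transcriptional landscape of marrow cells. Mettl1 encodes the catalytic subunit of the methyltransferase that places N7-methylguanosine at internal positions of tRNA, and Wdr4 encodes its partner subunit. The control library, called WT, came from Mettl1+/+ Mx1-Cre mice and the other, called M1, from Mettl1fl/fl Mx1-Cre littermates, all female C57BL/6J mice aged 6 weeks. Mx1-Cre is a recombinase switched on by interferon, which injected poly(I:C), a mimic of double-stranded RNA, induces. The mice received 7 injections of 10 mg/kg, marrow was taken 4 weeks after the last one, red cells were lysed, and cells of 3 mice were pooled into 1 library per genotype. The WT library held 335773218 UMIs over 28009 barcodes with a median of 8324 UMIs and 2685 genes per barcode. In the M1 library there were 356523600 UMIs over 29288 barcodes, with medians of 8523.5 UMIs and 2731 genes. The files hold 8009 and 9288 more barcodes than the 20000 cells said to be loaded for each. After filtering and removal of called doublets, 26123 WT and 27004 M1 cells remained. With 1 pooled library per genotype there is no replicate, so no difference was tested, and every interval is a 95% interval that covers counting error only.

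The first comparison asked how far the targeted transcript was lower in M1. Mettl1 (ENSMUSG00000006732), a protein-coding gene on the plus strand of chromosome 10 from 127041414 to 127046365 in GRCm38, was at 14.6 CPM (counts scaled to a fixed total of UMIs in the same cells; 14.13 to 14.98; 4543 UMIs) in WT cells and at 8.72 CPM (8.40 to 9.04; 2845 UMIs) in M1 cells. The M1/WT ratio was 0.599 (0.571 to 0.628). Wdr4, on the minus strand of chromosome 17 from 31494322 to 31519980, had a ratio of 0.947 (0.895 to 1.00). Among the 15 classes with enough cells to compare, the Mettl1 level was highest in HSC/progenitor-like cells, at 45.4 CPM in WT and 30.4 CPM in M1, a ratio of 0.67 (0.56 to 0.81), and in granulocyte-monocyte progenitor/promyelocyte-like cells the ratio was also 0.67 (0.59 to 0.76). In erythroid-like cells it was 41.8 CPM in WT and 20.7 CPM in M1, a ratio of 0.49 (0.45 to 0.54). Ratios were also low in immature neutrophil-like cells, at 0.19 (0.08 to 0.42) from 41 and 8 UMIs (-2.37 on the log2 scale, or -1.28 with doublets kept), and in NK/innate lymphoid-like cells, at 0.41 (0.23 to 0.70). Levels were 0.50 and 0.10 CPM in immature and 0.66 and 0.22 CPM in mature neutrophil-like cells, under the 10 CPM needed of a measured gene. Whether free RNA supplied these UMIs was not tested. The ratio was 0.59 (0.50 to 0.70) in immature/mature B-like, 0.67 (0.60 to 0.75) in monocyte-like and 0.84 (0.71 to 1.00) in pro/pre-B-like cells. The intervals of basophil/mast cell-like cells (0.91, 0.49 to 1.65) and plasmacytoid dendritic-like cells (0.74, 0.54 to 1.01) took in equal levels, and macrophage-like cells held 11 UMIs in WT and 0 in M1, under the floor of 3 counts. In the 2 classes too small to compare, no lower level was detectable at this depth: plasma cell-like cells were at 26.3 and 33.7 CPM (1.28, 0.927 to 1.79; 56 and 121 UMIs), and stromal/endothelial-like cells held 1 and 5 UMIs (2.09, 0.234 to 98.9). The labels do not give the exons flanked by loxP, so a 3' tag counted here may lie outside the deleted part, and the remaining UMIs cannot be read as cells that kept the gene.

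**Figure D1:**
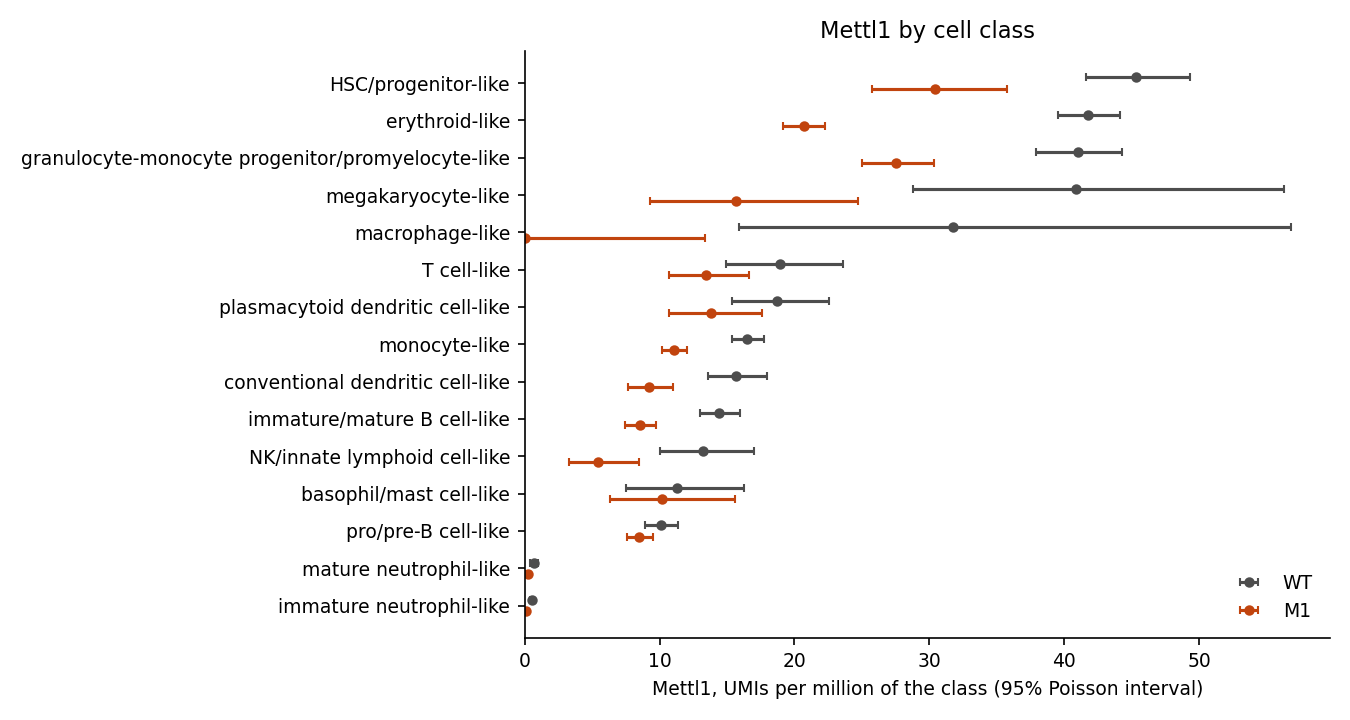
Mettl1 level in CPM of each class (x axis, with 95% Poisson intervals) in the compared cell classes (y axis) of the WT and M1 libraries. The M1 point lies left of the WT point in each class plotted; in HSC/progenitor-like cells the levels were 45.4 and 30.4, and in erythroid-like cells 41.8 and 20.7.

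The second comparison asked whether the make-up of the marrow differed. HSC/progenitor-like cells were the class with the lowest M1/WT ratio of shares: 369 cells or 1.41% (1.27 to 1.56) in WT and 151 cells or 0.559% (0.474 to 0.656) in M1, a ratio of 0.396 (0.325 to 0.480). Clustered again without the 973 genes that differed between the libraries within a class, the ratio was 0.393. At resolution 0.5, and in M1 clustered alone, no HSC/progenitor-like class formed. Counted without clusters, as cells with at least 5 of 15 fixed markers, the ratio was 0.491, or 0.640 without thinning to one depth. Granulocyte-monocyte progenitor/promyelocyte-like cells made up 1.78% and 1.73%, though the ratio was 0.732 at resolution 0.5 and 0.841 by per-cell marker score. Erythroid-like cells made up 2.87% and 2.89%, with a ratio of 0.743 for libraries clustered alone and 1.22 without the genes that differed. Within the erythroid-like class, the cluster rich in haemoglobin transcripts had 532 and 681 cells (ratio 1.24), and a cluster of low UMI counts had 217 and 99 (ratio 0.441). Immature neutrophil-like cells (24.8% and 24.0%) and mature neutrophil-like cells (25.6% and 26.5%) were the most frequent in both libraries, with ratios of 0.967 (0.934 to 1.00) and 1.03 (0.999 to 1.07).

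In the lymphoid classes, pro/pre-B-like cells stood higher in M1, at 10.8% against 9.22% (ratio 1.18, 1.11 to 1.24), while immature/mature B-like cells were at 12.3% against 12.95% (0.948, 0.904 to 0.995). Among the pro/pre-B-like clusters, cluster 15, with Myl4 and the histone gene Hist1h1a among its leading genes, had 530 WT and 838 M1 cells (ratio 1.53). The early pro-B-like cluster, led by Vpreb1, Igll1 and Dntt, had 258 and 337 (ratio 1.26). T-like cells made up 1.71% in WT and 2.73% in M1 (ratio 1.60, 1.42 to 1.80), drawn from cluster 28, led by Themis and Cd8b1, with 401 and 586 cells, and from cluster 33 with 45 and 152. Cluster 33 was led by Il23r, Gata3, Cxcr6 and Icos, and a Cd3e UMI was found in 31.1% of its WT and 42.1% of its M1 cells, so the cluster is not shown to hold T cells only. Lower shares in M1 were measured for NK/innate lymphoid-like cells (1.65% and 1.23%; ratio 0.747, 0.646 to 0.864), plasmacytoid dendritic-like cells (1.71% and 1.34%; 0.781, 0.678 to 0.900), macrophage-like cells (1.07% and 0.841%; 0.787, 0.658 to 0.941) and basophil/mast cell-like cells (0.812% and 0.641%; 0.789, 0.642 to 0.970). Conventional dendritic-like cells (2.60% and 2.47%) and megakaryocyte-like cells (0.7503% and 0.674%) had intervals of the ratio that took in 1, and monocyte-like cells were at 9.45% and 10.0% (ratio 1.06, 1.00 to 1.12). Stromal/endothelial-like cells (0.360% and 0.507%; 1.41, 1.08 to 1.85) were few, at 94 and 137 cells. Cluster 31, left without a name and led by Nrg1, a gene that itself differed between the libraries, held 0.877% of WT and 0.293% of M1 cells. Clustered alone, the libraries gave the opposite direction for the NK/innate lymphoid-like (2.07) and T-like (0.166) classes. The monocyte-like ratio also turned, to 0.780, and that of stromal/endothelial-like cells to 0.415, while at resolution 0.5 the NK/innate lymphoid-like ratio was 1.07 and the T-like 3.27, and at resolution 2 the monocyte-like 0.992.

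**Figure D2:**
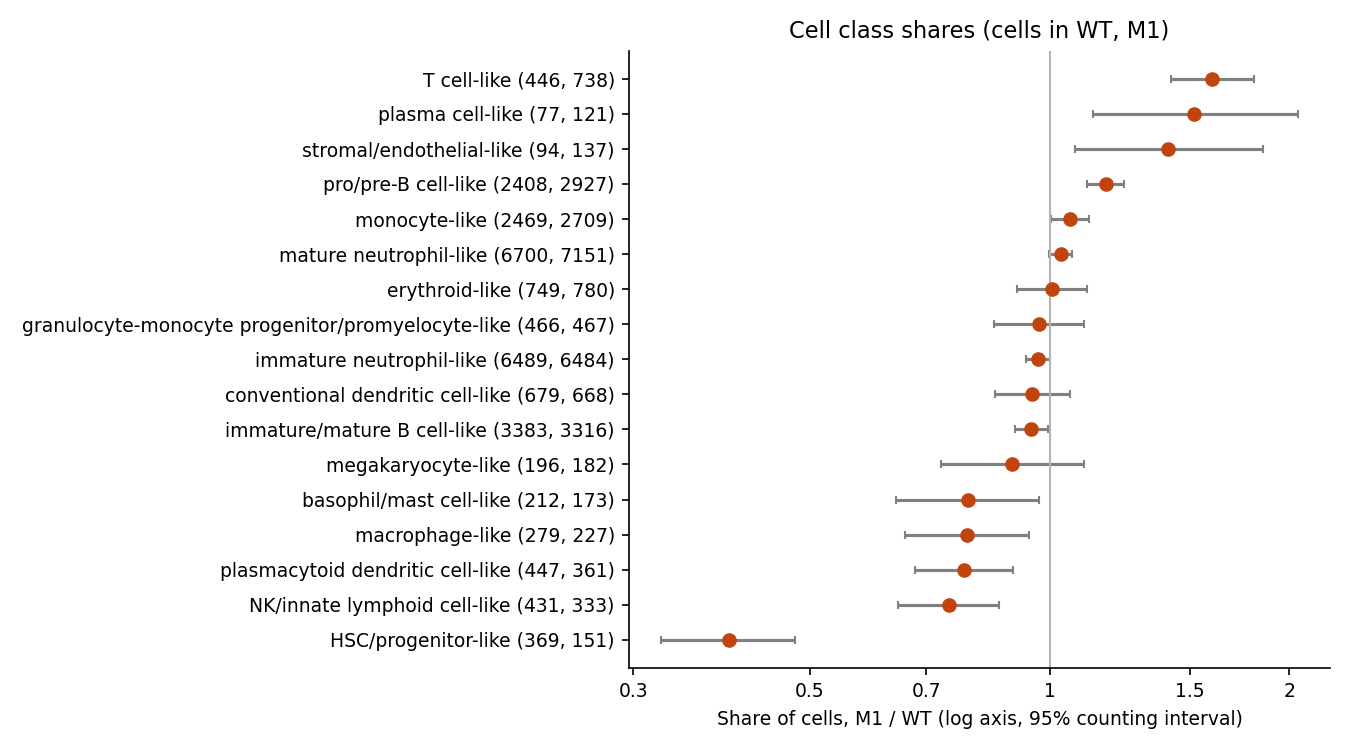
Ratio of the share of cells in M1 to that in WT (x axis, log scale, with 95% counting intervals) for each named cell class (y axis, with the cells in WT and M1). HSC/progenitor-like cells lie lowest at 0.396, and T-like cells highest at 1.60.

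The third comparison asked which genes differed within the cell classes. Of 8229 genes measured in at least 6 of the 15 compared classes, 223 had the same sign of log2(M1/WT) in each class measured, 129 above and 94 below 0. The gene with the highest median was Tmtc2, an endoplasmic reticulum protein of O-mannosylation, at 0.81 over 13 classes; it lies on chromosome 10 from 105187663 to 105574451, the chromosome of Mettl1. Vill had a median of 0.63, Gmfg, which acts on branched actin, 0.58 over all 15 classes, and Cpt1a, the enzyme that lets long-chain fatty acids enter mitochondria, 0.57 over 14. Tmem176a (0.57) and its neighbour Tmem176b (0.41), Filip1l (0.49 over 15 classes), Eps8l1 (0.48) and the interferon-inducible transcript AW112010 (0.46) were also among the 10 highest. The T cell adaptor Skap1, the remaining gene of the 10, had a median of 0.59 over 6 classes, in 2 of which 5 cells held over 50% of its UMIs, and was at 0.02 in T-like and 0.10 in NK/innate lymphoid-like cells, where it was most abundant. Lowest were the adhesion molecule Ncam1 (-1.10), Eda (-0.93), Cdk5rap1 (-0.89 over 12 classes), Aff2 (-0.87), the imprinted antisense RNA Airn (-0.64), Trim5 (-0.62), Mettl1 itself (-0.58 over 9), the histone gene Hist1h2ap (-0.54), Peli2 (-0.53) and the fatty acid desaturase Scd2 (-0.51 over 11). Cdk5rap1 is itself an RNA-modifying enzyme, which adds methylthio groups to mitochondrial tRNA.

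Among myeloid cells Nrg1, which encodes the growth factor neuregulin, was lower in each of 3 classes in which it was measured. In monocyte-like cells Nrg1 was at 305 CPM in WT and 53.8 CPM in M1 (ratio 0.18, 0.17 to 0.18), in granulocyte-monocyte progenitor/promyelocyte-like cells at 58.7 and 5.91 CPM (0.10, 0.08 to 0.13) and in conventional dendritic-like cells at 37.6 and 1.82 CPM (0.05, 0.03 to 0.07), a log2 ratio of -4.37, or -3.23 as means of per-cell CPM. Monocyte-like cells of M1 also had lower Shtn1 (22.7 and 6.63 CPM) and Adam19 (50.8 and 15.1 CPM), and higher Chil3 (438 and 864 CPM), the proteoglycan Vcan (81.6 and 149 CPM) and Pla2g7 (28.5 and 64.3 CPM). Granulocyte-monocyte progenitor/promyelocyte-like cells of M1 had lower Tfpi (ratio 0.33) and Rnf217 (0.36) and higher Atf5 (2.08), H2-Q7 (29.5 and 78.8 CPM) and H2-Q6 (ratio 2.31). H2-Q6 and H2-Q7 are MHC class I paralogs that can share reads. Both were higher in mature neutrophil-like cells, with ratios of 3.81 and 3.42, and H2-Q7 in immature ones (2.77). In neutrophils low ratios were found for Bmpr1a, a receptor for bone morphogenetic proteins, and Olfm4, a granule protein known to mark a subset of neutrophils. In immature neutrophil-like cells Bmpr1a was at 102 and 18.5 CPM (0.18, 0.17 to 0.19), Olfm4 at 316 and 67.9 CPM (0.21, 0.21 to 0.22) and Ugt8a at 18.4 and 2.47 CPM (0.13, 0.12 to 0.16). Mature neutrophil-like cells had Olfm4 at 130.5 and 36.8 CPM, Bmpr1a at a ratio of 0.21 and Cdk5rap1 at 26.2 and 6.50 CPM. Filip1l was higher in both neutrophil classes, with ratios of 1.81 and 1.97.

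In pro/pre-B-like cells Col25a1 was at 112 CPM in WT and 27.3 CPM in M1, Auts2 at 168 and 43.7 CPM, and the stem cell transcription factor Meis1 at 23.3 and 4.52 CPM (0.19, 0.16 to 0.23). In immature/mature B-like cells Col25a1 (ratio 0.32), Camk2b (0.40) and Reln (119 and 43.2 CPM) were lower, and Nid1 (2.42), Skap1 (1.89) and Tmtc2 (1.87) higher. The X-linked genes Pcdh11x and Mid1 had ratios of 3.20 and 2.12 in pro/pre-B-like cells, beside Tmtc2 at 2.24. Erythroid-like cells had lower Khdrbs3 (29.8 and 7.09 CPM), Gpc4 (132 and 39.5 CPM; 0.30, 0.28 to 0.32) and Ube2e2 (ratio 0.31), and higher Gnasas1 (2.52), Rnf17 (2.38) and Tmtc2 (2.08). HSC/progenitor-like cells had lower Mmrn1 (56.3 and 9.60 CPM) and higher Tjp1 (16.2 and 49.2 CPM) and Gnasas1 (3.07). Plasmacytoid dendritic-like cells had lower Egfem1 (ratio 0.05; log2 -4.35, or -3.67 as means of per-cell CPM), Agbl1 (174 and 17.2 CPM) and Sdc2 (0.13), and higher Cd84 (2.24). NK/innate lymphoid-like cells had higher Klrb1b (2.84), the chemokine receptor Cxcr6 (2.15) and Inpp4b (410 and 877 CPM), and lower Mef2c (0.33).

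Basophil/mast cell-like cells had higher Scin (2.57) and lower Plcb1 (0.29) and Mir99ahg (0.36), macrophage-like cells higher Psmb8 (2.01) and Sumo2 (2.01), megakaryocyte-like cells lower Kif15 (0.42) and T-like cells higher Pram1 (7.89, or 2.37 in place of 2.98 on the log2 scale with doublets kept) and Enah (7.88), beside free RNA markers of granulocytes at a median log2 ratio of 0.84 in that class. For the remaining genes that the rule named, 5 cells held over 50% of the UMIs in the higher library. They were Jchain, Ppp2r2b and Pde3a in HSC/progenitor-like cells, Mki67 and Top2a in NK/innate lymphoid-like cells, Skap1 and Bank1 in plasmacytoid dendritic-like cells, and Pax5, Ptprm, Gpm6b and Xcl1 in T-like cells. The same held for Prtn3, Elane and Prg2 in basophil/mast cell-like cells, for Ctsk, Atp6v0d2, Acp5, Hbb-bt and Hbb-bs in conventional dendritic-like cells, for Cxcl9, Chil3, Hbb-bs and Wfdc21 in macrophage-like cells and for Neb, Pde7b, Rasgrp3, Chil3 and Camp in megakaryocyte-like cells.

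Shares of cells with a UMI were compared after each cell was thinned to 3000 UMIs. Nrg1 was then found in 34.5% (32.6 to 36.5) of WT and 8.13% (7.11 to 9.26) of M1 monocyte-like cells, against 0.319% and 0.112% of pro/pre-B-like cells, which served as background. Before thinning the shares were 54.1% and 15.4%, at median depths of 16205 and 15432 UMIs; the background class had medians of 7551.5 and 8055. Thinning left out 144 WT and 127 M1 cells. In granulocyte-monocyte progenitor/promyelocyte-like cells Nrg1 was in 15.6% and 1.72%. Bmpr1a was in 25.7% and 5.13% of immature neutrophil-like cells (51.1% and 11.9% unthinned), with a background of 0.502% and 0.0749%, and Olfm4 in 10.1% and 2.77% (14.8% and 3.78% unthinned), with a background of 1.64% and 0.187%. Gpc4 was in 29.3% and 9.03% of erythroid-like cells (65.6% and 25.1% unthinned), with a background of 0.183% and 0.0375%.

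**Figure D3:**
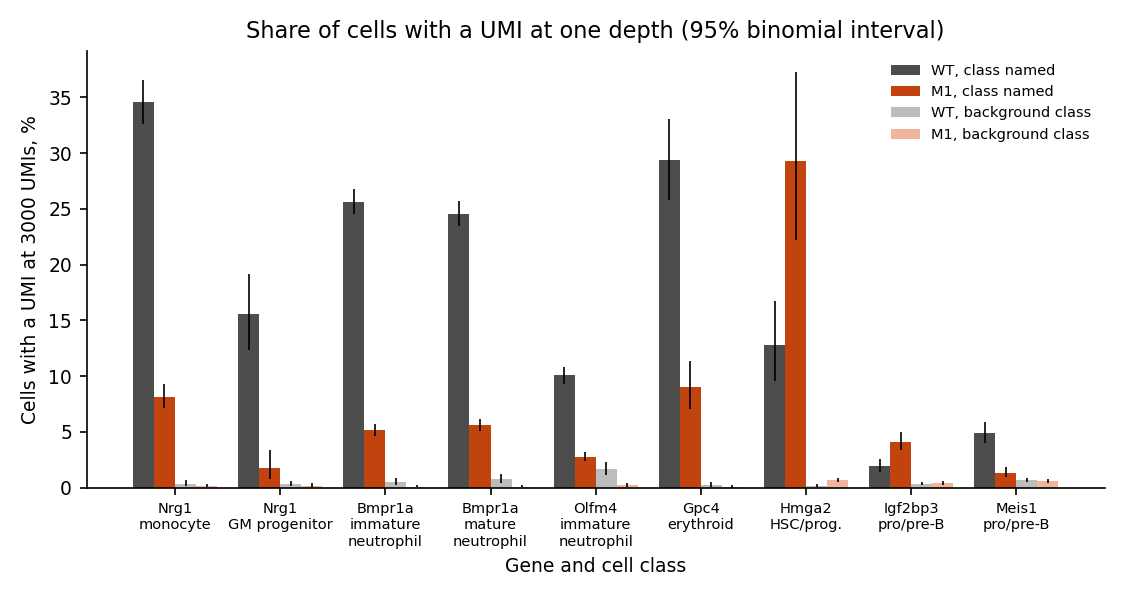
Percent of cells with a UMI of a gene after thinning to 3000 UMIs (y axis, bars from 0, with 95% binomial intervals) for gene and class pairs (x axis) in WT and M1, beside a class taken as background. Nrg1 fills 34.5% of WT and 8.13% of M1 monocyte-like cells, and Hmga2 12.8% and 29.3% of HSC/progenitor-like cells.

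The fourth comparison placed fixed gene lists within the classes. A list's median log2(M1/WT) was set among 10000 random lists matched on expression, and the places given describe these 2 libraries only. A member's median was taken over the classes in which it was measured, at least 3. The highest and lowest members can thus rest on few classes, with values of both signs. Ribosomal proteins, cytosolic and mitochondrial, and proteasome subunits were slightly higher in most classes of M1. The 79 measured cytosolic ribosomal protein genes had a median over classes of 0.11 and were above 0 in 14 of 15 classes, in the top 2.5% in 12. Apart from macrophage-like cells (0.37), with medians of 807 and 815 UMIs per cell, the largest medians were in basophil/mast cell-like (0.25), pro/pre-B-like (0.22, where each of the 79 was above 0) and HSC/progenitor-like cells (0.17, 75 of 79 above 0). Cluster 15, with a median of 17498 UMIs, held 530 of the 2408 WT and 838 of the 2927 M1 pro/pre-B-like cells. Cluster 7 of that class had a median of 6845 UMIs. Lists were not split by cluster there, so part of the pro/pre-B-like value of this and other lists may go with the mix. In T-like cells the median was 0.02, and -0.01 with trimmed-mean scaling. Rpl29 (median over classes 0.35) and Rpl10 (0.31) were highest, Rps21 (-0.10) and Rpl38 (-0.08) lowest. Mitochondrial ribosomal proteins had a median of 0.09 (13 of 15 classes above 0), with Mrps11 (0.30) and Mrpl46 (0.25) highest and Mrpl10 (-0.11) and Mrps28 (-0.10) lowest. Proteasome subunits stood at 0.12 (14 of 15 classes above 0, none in the bottom 2.5%). Among them the immunoproteasome subunits Psmb8 (0.36) and Psmb9 (0.26) were highest and the regulatory subunits Psmd2 (-0.13) and Psmd3 (-0.11) lowest. Translation factors had a median of 0.04, with the translational repressor Eif4ebp1 (0.26) and Eif3f (0.25) highest and Eef1aknmt (-0.21) and the stress kinase Eif2ak4 (-0.14) lowest. Ribosome biogenesis factors stood at 0.02, from Npm1 (0.30) and Mrto4 (0.25) to Rrp9 (-0.19) and Rrp12 (-0.15), and went both ways by class, in the top 2.5% in 6 classes and the bottom 2.5% in 3. They were at 0.15 in pro/pre-B-like cells, -0.19 in erythroid-like cells with 35 of 36 below 0, and -0.07 in conventional dendritic-like cells. Megakaryocyte-like cells, with medians of 1689 and 1698.5 UMIs per cell, went the other way for many lists, at -0.61 for ribosomal proteins, or -0.49 with trimmed-mean scaling, whose log2 factor of -0.12 there is taken off each gene's value. In immature neutrophil-like cells the ratio also followed gene length (Spearman -0.43 across genes, which are not independent replicates), so part of these small medians goes with shorter genes. The correlation was -0.46 in macrophage-like, -0.40 in pro/pre-B-like and -0.30 in HSC/progenitor-like cells. It was -0.14 in T-like, -0.06 in NK/innate lymphoid-like and 0.35 in megakaryocyte-like cells.

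Antigen presentation genes were higher in most classes as well. MHC class I genes had a median of 0.18 and were above 0 in 14 of 15 classes, with 0.53 in basophil/mast cell-like, 0.35 in mature neutrophil-like and 0.32 in granulocyte-monocyte progenitor/promyelocyte-like cells, and -0.07 in plasmacytoid dendritic-like cells. H2-Q7 (0.38) and Psmb8 were highest, Tap2 (-0.07) and H2-Q6 (-0.05) lowest by median over classes. The MHC class II list was at 0.46 in conventional dendritic-like cells, where all 12 members were above 0, at 0.23 in monocyte-like and 0.19 in immature/mature B-like cells, but at -0.13 in plasmacytoid dendritic-like (8 of 11 below 0), -0.09 in HSC/progenitor-like and -1.53 in megakaryocyte-like cells. Within immature/mature B-like cells the list was at 0.04 in cluster 3, led by Fcer2a and Cr2, which was larger in M1 (1206 and 1424 cells) and richest in these transcripts, and at 0.12 in cluster 9 (2104 and 1822 cells), so part of the 0.19 goes with the mix of clusters. Within the conventional dendritic-like clusters it was at 0.54 and 0.35. Its median over 10 classes was 0.21, or 0.062 with low genes kept. H2-Eb1 (0.36) and H2-Ab1 (0.34) were highest, and H2-Ob (0.05) and Ifi30 (0.12) lowest. The T-like value of 1.08 stood beside B cell transcripts in that class: a Pax5 UMI was found in 8.02% of the M1 and 0.249% of the WT cells of cluster 28.

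Cholesterol synthesis genes were lower in M1 in 11 of 14 classes, with a median of -0.24 and a place in the bottom 2.5% in 9. The list was at -0.36 in granulocyte-monocyte progenitor/promyelocyte-like, -0.35 in immature neutrophil-like, -0.34 in erythroid-like, -0.33 in monocyte-like, -0.30 in mature neutrophil-like and -0.29 in HSC/progenitor-like cells, and in none of these 6 classes was a measured member above 0. Among its members Hmgcs1, an early enzyme of the pathway, had a median over classes of -0.13. B-lineage and T-like classes had medians from -0.09 to 0.01, while NK/innate lymphoid-like cells were at 0.22 and megakaryocyte-like cells at 0.65. As means of per-cell CPM the median over classes was -0.15.

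Haematopoietic stem cell genes had a median of -0.12 over 12 classes, or -0.19 with low genes kept, with doublets kept and without the macrophage-, megakaryocyte- and T-like classes. Within HSC/progenitor-like cells 14 of 16 measured members were below 0 (median -0.21), among them Ctnnal1 at a ratio of 0.58 (0.43 to 0.76). Slamf1 (1.18, 0.94 to 1.47) and Hoxa9 (1.08, 0.94 to 1.25) were the 2 above 0. Of this list, 13 of 20 genes are also cell type markers used to name clusters. Meis1 was the lowest member over classes, with a median of -0.75. Ly6a (0.29) and Slamf1 (0.25) were highest over classes. In megakaryocyte-like cells the list was at 0.89.

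Proliferation lists differed by class. In pro/pre-B-like cells S-phase genes had a median of 0.22, G2/M-phase genes 0.24 and core histone genes 0.38, beside a cluster 15 that was larger in M1. These lists were not measured by cluster. In megakaryocyte-like cells S-phase genes were at -0.71 and G2/M-phase genes at -0.70, with no measured member above 0. In NK/innate lymphoid-like cells G2/M-phase genes were at -0.55, where 5 cells held over 50% of the WT UMIs of Mki67 and Top2a. In plasmacytoid dendritic-like cells S-phase genes were at 0.30, and G2/M-phase genes were at 0.20 in conventional dendritic-like, -0.15 in immature/mature B-like and -0.21 in basophil/mast cell-like cells. Over classes the medians were -0.0041 for S phase, from Tyms (0.17) and Clspn (0.11) to Ung (-0.22) and Uhrf1 (-0.13), and -0.03 for G2/M, or 0.01 with trimmed-mean scaling, from Psrc1 (0.21) and Ccnb2 (0.18) to Aurka (-0.14) and Nek2 (-0.13). Core histone genes had a median of 0.06, or 0.0062 with low genes kept and 0.15 as means of per-cell CPM, and reached 0.36 in mature neutrophil-like cells, which no longer divide; Hist1h2bb (0.38) and Hist1h2ac (0.35) were highest and Hist1h2ap and Hist1h2af (-0.12) lowest.

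Stress and signalling lists showed medians over classes close to 0, with values of both signs by class. The ATF4 targets of the integrated stress response had a median of -0.02, with values of 0.13 in HSC/progenitor-like and 0.16 in pro/pre-B-like cells, both in the top 2.5%, and of -0.19 in erythroid-like, -0.11 in T-like and -0.07 in immature/mature B-like cells, all in the bottom 2.5%. Ppp1r15a (0.24) and Herpud1 (0.11) were highest, and the amino acid transporter gene Slc7a5 (-0.18) and asparagine synthetase Asns (-0.18) lowest. The p53 targets stood at -0.01, with Cdkn1a (0.32) and Bax (0.18) highest and Ei24 (-0.21) and Zmat3 (-0.17) lowest, and were at 0.15 in NK/innate lymphoid-like and -0.09 in immature/mature B-like cells. Type I interferon-stimulated genes were at -0.03, or 0.0017 with trimmed-mean scaling, from Iigp1 (0.50) and Ly6a to Ifi27l2a (-0.42) and Oas3 (-0.32), but lay in the outer 2.5% in 8 of 15 classes. They were at -0.17 in pro/pre-B-like, -0.15 in HSC/progenitor-like, -0.14 in conventional dendritic-like (35 of 39 below 0) and -0.12 in immature/mature B-like cells, and at 0.14 in plasmacytoid dendritic-like and 0.57 in megakaryocyte-like cells. Unfolded protein response genes had -0.0044, with Manf (0.19) and Dnajb11 (0.14) highest and Canx (-0.08) and Syvn1 (-0.07) lowest, and were at 0.22 in T-like and -0.19 in erythroid-like cells, where 18 of 19 were below 0. NF-kB genes had -0.02, from Bcl2a1d (0.68) and Ccl4 (0.67) to Tnfaip3 (-0.31) and Nfkbiz (-0.20), and were at -0.27 in plasmacytoid dendritic-like and -0.12 in pro/pre-B-like cells. Immediate-early genes stood at 0.02, from Socs3 (0.60) and Fos (0.24) to Rgs1 (-0.37) and Egr1 (-0.22). Apoptosis regulators were at -0.0012, with Bad (0.26) and Bax above and Bcl2l1 (-0.12) and Bid (-0.11) below. Some members named here were measured in 3 classes only: Ppp1r15a, Cdkn1a, Zmat3, Ccl4, Socs3, Fos and Egr1. Ccl4 ranged from -0.73 to 1.49 and Egr1 from -0.27 to 0.86. Bcl2a1d and Rgs1 were measured in 4.

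The tRNA-related and metabolic lists had medians over classes of at most 0.06 in size, with larger values in single classes. Other tRNA modification enzymes had a median of -0.02, with Ftsj1 (0.16) and Trmt10a (0.12) highest and Ctu2 (-0.29) and Wdr4 (-0.19) lowest. Ctu2 was measured in 3 classes (-0.48 to 0.48) and Wdr4 in 4 (-0.24 to 0.0033). These enzymes were at 0.10 in pro/pre-B-like cells and at -0.61 in megakaryocyte-like cells, where 11 of 12 were below 0. The fixed list does not hold Cdk5rap1, the mitochondrial tRNA enzyme whose median was -0.89 over 12 classes. Cytosolic aminoacyl-tRNA synthetases had -0.0045, from Aimp2 (0.22) and Iars (0.08) to Farsb (-0.13) and Yars (-0.12), and were at -0.13 in erythroid-like cells (20 of 22 below 0) and 0.08 in HSC/progenitor-like cells. Mitochondrially encoded genes stood at 0.06, above 0 in 13 of 15 classes, at 0.30 in basophil/mast cell-like and -0.23 in macrophage-like cells, with mt-Co3 (0.27) and mt-Nd6 (0.24) highest and mt-Nd3 (-0.12) and mt-Atp8 (-0.09) lowest. Nuclear-encoded oxidative phosphorylation genes were at 0.03, above 0 in 14 of 15 classes and in the top 2.5% in 9, at 0.14 in pro/pre-B-like and 0.09 in HSC/progenitor-like cells, from Ndufs8 (0.29) and Cox7a2l (0.21) to Ndufa1 (-0.18) and Atp5k (-0.16). Glycolysis genes had a median of 0.02, from Eno1 (0.25) and Gapdh (0.24) to the glucose transporters Slc2a1 (-0.28) and Slc2a3 (-0.10), and were at -0.15 in erythroid-like and 0.11 in HSC/progenitor-like cells. In megakaryocyte-like cells synthetases were at -0.60, mitochondrially encoded genes at -0.72 and oxidative phosphorylation genes at -0.58, while glycolysis genes were at 0.18. The chromosomal neighbours of Mettl1 had a median of 0.01, with Cdk4 (0.12) and Tspan31 (0.12) highest and Dtx3 (-0.08) and Agap2 (-0.06) lowest. Pre-B receptor and V(D)J recombination genes were at -0.0037, or 0.0023 with trimmed-mean scaling, from Vpreb3 (0.14) and Ebf1 (0.10) to Dntt (-0.18) and Foxo1 (-0.16), and were at 0.75 in T-like cells, beside the B cell transcripts there. Monocyte/macrophage genes stood at 0.02, or -0.12 with low genes kept, with Lyz2 (0.21) and Ms4a6c (0.19) highest and F13a1 at -0.15, and were at 0.23 in HSC/progenitor-like and -0.24 in pro/pre-B-like cells.

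Lists of the abundant granulocyte and red cell transcripts were read beside free RNA, because an S100a8 UMI was found in 98.7% of WT and 97.9% of M1 pro/pre-B-like cells. The 7 free RNA markers had a median of -0.10 over classes, or -0.01 with trimmed-mean scaling, from Retnlg (0.35) and Lcn2 (0.16) to S100a8 (-0.12) and Camp (-0.11). They lay in the top 2.5% in 5 classes and the bottom 2.5% in 7, at 0.84 in T-like, 0.66 in plasmacytoid dendritic-like and 0.53 in conventional dendritic-like cells, and at -0.97 in macrophage-like, -0.36 in pro/pre-B-like, -0.32 in immature/mature B-like and -0.30 in HSC/progenitor-like cells. Primary granule genes had a median of -0.44, or -0.060 without the macrophage-, megakaryocyte- and T-like classes, with Elane (-0.74) and Mpo (-0.60) lowest and Lyz2 and Ms4a3 (0.07) highest. In the class that makes them, the granulocyte-monocyte progenitor/promyelocyte-like cells, the median was 0.11 and Elane stood at 12653 and 14104 CPM. In immature/mature B-like cells the list was at -0.72. An Elane UMI was found there in 28.1% of WT and 17.6% of M1 cells, at 45.1 and 25.5 CPM. That lower value thus sat in a class that holds Elane only at a low level. Erythroid-like cells, with Elane at 28.5 and 33.2 CPM, were at 0.22. Specific granule genes were at -0.03, or 0.02 with trimmed-mean scaling, from Hp (0.27) and Fcnb (0.22) to Camp and Chil3 (-0.04), and like the free RNA markers stood high or low by class, at 1.05 in T-like, 0.59 in plasmacytoid dendritic-like, 0.51 in conventional dendritic-like and -1.01 in macrophage-like cells. In the granulocyte-monocyte progenitor/promyelocyte-like class all 11 measured members were above 0 (median 0.28), and in immature neutrophil-like cells 11 of 12 (0.16). Late neutrophil maturation genes were at 0.04, or 0.077 with doublets kept, from Retnlg and Ccl6 (0.22) to Fpr2 (-0.17) and Stfa2l1 (-0.09), and at -0.46 in pro/pre-B-like and 0.81 in megakaryocyte-like cells. Erythroid and haem genes had a median of 0.13, or 0.07 with low genes kept, with 0.17 in erythroid-like cells, from Hba-a2 (0.23) and Alad (0.20) to Car1 (-0.26) and Car2 (-0.20).

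**Figure D4:**
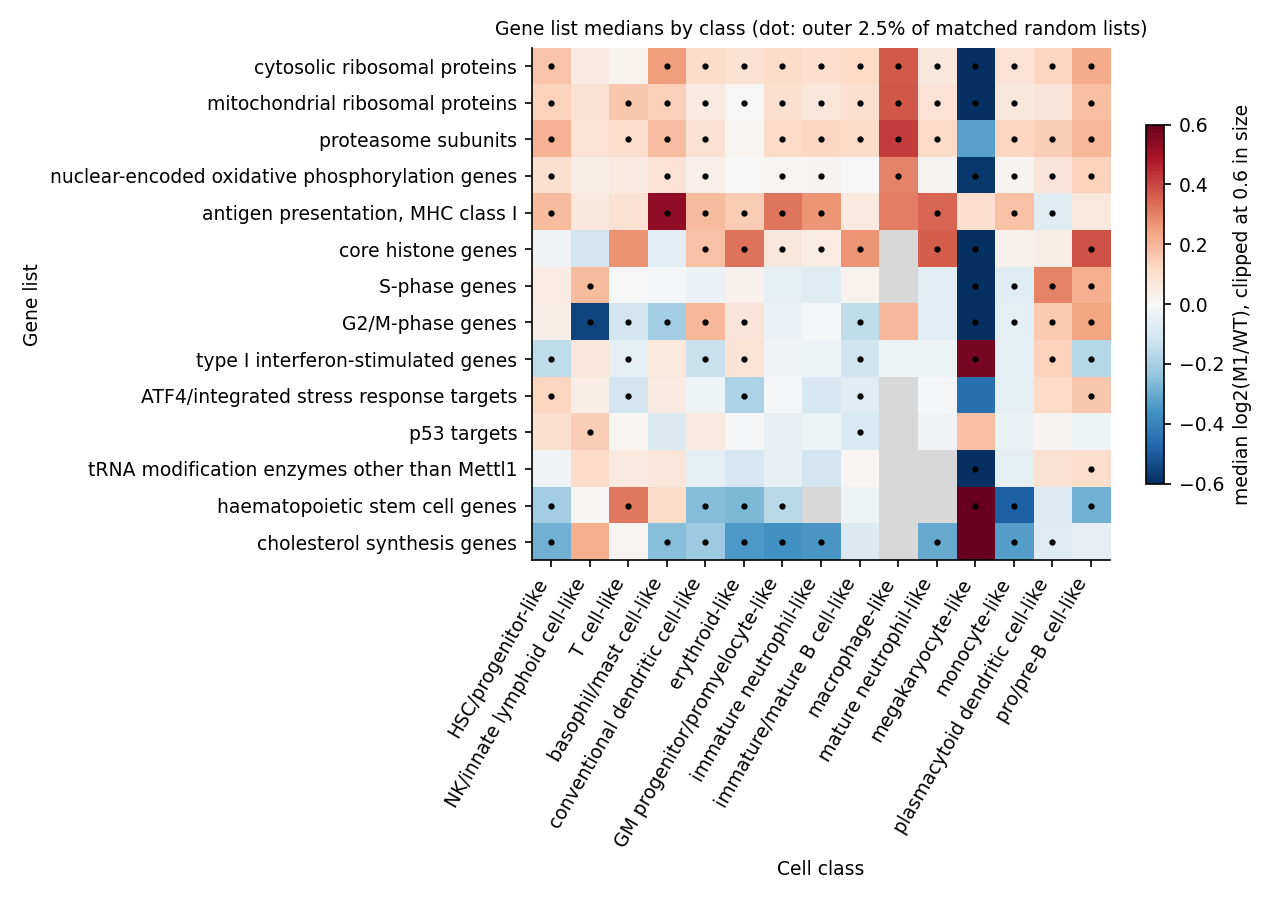
Median log2(M1/WT) of 14 fixed gene lists (y axis) in the compared cell classes (x axis), by colour; a dot marks a median in the outer 2.5% of matched random lists and grey a list with too few measured members. Cytosolic ribosomal proteins were above 0 in 14 of 15 classes, and cholesterol synthesis genes below 0 in 11 of 14.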

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

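The tests of low-UMI cell loss and of an even lowering of Nrg1 were chosen after those results were seen, as were the counts of HSC/progenitor-like cells without clusters. Values outside the comparisons were 1.68% (1.54 to 1.84) of M1 barcodes with over 10% mitochondrially encoded UMIs, against 1.30% in WT. Called doublets were 6.06% (5.79 to 6.35) of M1 barcodes, against 5.48% in WT. Plasma cell-like cells made up 0.448% (0.372 to 0.535) of M1 cells, against 0.295% of WT cells, too few there to compare expression; by per-cell marker score the ratio was 1.04 in place of 1.52. What set these 3 values apart was an M1 interval above that of WT, the control library.

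HSC/progenitor-like cells were fewer in M1 (ratio of shares 0.396). A border drawn by the clustering was examined by a count of cells with at least 5 of 15 fixed markers after thinning to 5000 UMIs. It was met by 346 of 20244 WT and 179 of 21310 M1 cells. The ratio was 0.491 with an upper bound of 0.590 (0.640 and 0.712 unthinned). The counted markers are those that name the class, so lower marker levels would cut this count as they would move a border. Since 13 of the 15 markers were lower in M1 cells of the class, the markers of WT cells were also lowered to the M1 level, which gave 0.520 (0.431 to 0.626). That level was read from M1 cells inside the class, so cells with still lower markers outside it would not be covered. The lowered count therefore adds no weight against a border. Neither count can tell fewer cells from cells with lower markers, so a border stays open. Clusters 30 and 31, at medians of 3701 and 4113.5 UMIs, were also smaller in M1 (ratios 0.441 and 0.334), but a loss of low-UMI cells as the cause for HSC/progenitor-like cells is argued against by those with at least 8275 UMIs, the WT median, whose ratio was 0.4001 (0.326 to 0.489) from 330 and 140 cells. A difference between the pooled mice apart from genotype cannot be told apart from the genotype, since there is 1 pool for each.

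Nrg1-positive monocyte-like cells were fewer in M1, and an even thinning of Nrg1 UMIs in every cell of that class is argued against. After each WT cell's Nrg1 UMIs were thinned to the M1 mean, 35.4% of WT cells would still be positive. That is 20.01 percentage points more than the 15.4% found in M1. In granulocyte-monocyte progenitor/promyelocyte-like cells the values were 14.9% and 7.92%. This gap of 6.97 points lay within the margin set for an even lowering, which stays open in that class. The thinning models fewer UMIs in each positive cell. A lower chance of expression shared by all cells was not modelled and is not excluded. Free RNA is argued against by the WT pro/pre-B-like cells, of which 0.872% held an Nrg1 UMI, against 54.1% of monocyte-like cells. The idea that the positive M1 cells escaped recombination found no trace in Mettl1, whose level in Nrg1-positive over Nrg1-negative M1 cells of the same clusters was 0.940 (0.769 to 1.14), although a 3' tag outside the deleted part could hide it. Whether the pooled mice differed from each other in Nrg1 was not tested, and such a difference may account for the pattern as well as the genotype.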

How the results depend on the processing

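The HSC/progenitor-like counts without clusters, the erythroid-like class without its low-UMI cluster, the clustering without differing genes and the list medians without 3 classes were chosen after the results were seen. No paired analysis was possible because there is 1 library per group and no test. The Mettl1 ratio stayed within its interval with all deposited barcodes (0.6002) and with scaling without abundant genes (0.601). For shares, 17 of 17 classes stayed within their intervals with no cell filter, the stricter filter or doublets kept, and 15 of 15 among cells outside the neutrophil classes. These settings were not clustered again: cells kept their class, and added barcodes took that of the most correlated cluster. The neutrophil classes together made up nearly the same part of both libraries. Such settings could thus move the shares little, and their stability does not bear on the clustering.

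At resolution 0.5 the NK/innate lymphoid-like ratio reversed to 1.07, and the T-like moved to 3.27, basophil/mast cell-like to 0.537, granulocyte-monocyte progenitor/promyelocyte-like to 0.732 and megakaryocyte-like to 1.25. No HSC/progenitor-, conventional dendritic- or stromal/endothelial-like class formed there. At resolution 2 the monocyte-like ratio reversed to 0.992. By per-cell score, conventional dendritic-like moved to 1.09, granulocyte-monocyte progenitor/promyelocyte-like to 0.841, immature neutrophil-like to 1.01 and plasma cell-like to 1.04. With libraries clustered alone, NK/innate lymphoid-like (2.07), T-like (0.166), monocyte-like (0.780) and stromal/endothelial-like (0.415) reversed. There, conventional dendritic-like moved to 1.33, erythroid-like to 0.743, immature neutrophil-like to 0.816, immature/mature B-like to 0.814, mature neutrophil-like to 1.13 and pro/pre-B-like to 1.35, and M1 gave no HSC/progenitor-like class. A further class also gave no ratio there, and only 5 classes stayed within their intervals. Without clusters the HSC/progenitor-like ratio was 0.491, or 0.640 without thinning and 0.520 with WT markers lowered to M1, and without its low-UMI cluster the erythroid-like ratio 1.24. Clustered without differing genes, conventional dendritic-like moved to 1.17, erythroid-like to 1.22 and megakaryocyte-like to 0.687. For these shares the cause was not tested.

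No list median with a counting interval away from 0 changed sign. With low genes kept, medians moved to 0.026 for ATF4 targets, 0.024 for p53 targets, -0.079 for interferon-stimulated, 0.053 for immediate-early, 0.0062 for histone, 0.062 for MHC class II, 0.033 for pre-B receptor, -0.19 for stem cell, 0.073 for erythroid and -0.12 for monocyte/macrophage genes and -0.033 for the neighbours of Mettl1. With means of per-cell CPM they moved to -0.040 for S-phase, 0.14 for ribosomal protein, 0.055 for translation factor, 0.038 for oxidative phosphorylation, 0.15 for histone, 0.090 for specific granule, 0.15 for MHC class II, 0.15 for MHC class I and -0.048 for monocyte/macrophage genes. With TMM factors G2/M-phase genes moved to 0.0060, ribosomal proteins to 0.12, mitochondrially encoded genes to 0.055 and oxidative phosphorylation genes to 0.038. With doublets kept G2/M-phase genes moved to 0.011, translation factors to 0.051, pre-B receptor genes to 0.027 and stem cell genes to -0.19. The stricter filter moved MHC class II to 0.23, and leaving out 3 classes moved glycolysis to 0.0047 and primary granule genes from -0.44 to -0.060. All 32 medians stayed within their intervals with scaling without abundant genes. Of 120 named gene values, 40 moved with means of per-cell CPM, 11 with doublets kept and 1 with TMM factors. None with an interval that excluded equal levels changed sign; Mettl1 in basophil/mast cell-like cells went from a log2 ratio of -0.14 to 0.020 with means of per-cell CPM. For the lists the cause was not tested. Depth limits the macrophage-, stromal/endothelial- and megakaryocyte-like classes most, at medians of 807, 1261.5 and 1689 UMIs per WT cell.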

Other observations

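The test that thinned WT counts to the M1 mean was chosen after the result was seen, and so were the genes Hmga2 and Igf2bp3. Both belong to a fetal programme of blood formation and are repressed by the microRNA let-7 in adult cells. Hmga2 was at 62.9 CPM in WT and 157 CPM in M1 HSC/progenitor-like cells, a ratio of 2.49 (2.25 to 2.76). At 3000 UMIs per cell an Hmga2 UMI was found in 12.8% (9.54 to 16.7) of WT and 29.3% (22.2 to 37.3) of M1 cells (32.2% and 58.9% unthinned), against 0.170% and 0.636% of mature neutrophil-like cells. Hmga2 was also higher in erythroid-like cells, with a ratio of 2.14 (1.48 to 3.14). In pro/pre-B-like cells its ratio was 2.27 (1.22 to 4.48) from 14 and 44 UMIs. In immature/mature B-like cells it was 0.328 (0.0324 to 1.83) from 6 and 2 UMIs. Igf2bp3 was at 9.27 and 18.9 CPM in pro/pre-B-like cells, a ratio of 2.04 (1.76 to 2.38), with 1.92% and 4.12% of cells positive at 3000 UMIs and 0.339% and 0.388% in the background class. In immature/mature B-like cells its ratio was 1.71 (1.45 to 2.03), and in HSC/progenitor-like cells 0.635 (0.185 to 1.76), from 19 and 5 UMIs.

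METTL1 has been reported to act on let-7 processing, so a weaker let-7 may be one hypothesis for Hmga2 and Igf2bp3. It was tested on the other let-7 targets of a list of 39 genes, which would then be higher as a group. The median of the 28 measured in HSC/progenitor-like cells was 0.04, at percentile 86.4 of matched random lists, and that of the 24 in pro/pre-B-like cells 0.02, at percentile 69.7. Higher let-7 targets as a group were thus not found in these libraries, and no other explanation was tested.

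The higher ribosomal, mitochondrial ribosomal and proteasome transcripts of M1 were weighed against technical causes. Pooled into one, the 3 lists stayed in the top 2.5% in 11 of 15 classes when random lists were matched on gene length as well. The match used 6 bins of expression by 6 of length. Genes within a bin can still differ in length, so length bias as the whole cause is not excluded there. In erythroid-, NK/innate lymphoid- and T-like cells, at percentiles 88.2, 82.4 and 73.9, the lists did not stand out from the length-matched ones. In megakaryocyte-like cells the 3 lists were below 0 (-0.55). Outside the megakaryocyte-like class, the length-matched random lists were themselves above 0. Their median was 0.05 in immature neutrophil-like cells, where the 3 lists had 0.09. It was 0.12 against 0.20 in pro/pre-B-like, 0.10 against 0.16 in HSC/progenitor-like and 0.26 against 0.37 in macrophage-like cells. Length may thus take a large part of these values. Scaling is argued against, since with trimmed-mean factors the 3 lists stayed above 0 in 14 of 15 classes. These transcript levels do not measure the output of either machinery, and whether the pooled mice differed apart from genotype was not tested. Nor was the mix of clusters within a class weighed for these lists.

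After WT counts were thinned to the M1 mean, the share of positive cells was 50.6% in WT against 25.1% in M1 for Gpc4 in erythroid-like cells. In immature neutrophil-like cells it was 18.8% against 11.9% for Bmpr1a and 9.69% against 3.78% for Olfm4. Of the 19 genes other than Mettl1 with the most extreme shared medians, 1 lay on chromosome 10, where 4.97% of the measured genes lie. Chromosomes 7 and 19 held 3 each, with 6.81% and 3.79% of the measured genes, and chromosomes 6, 9 and X held 2 each, with 4.79%, 5.47% and 3.06%.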
